A study of Homo sapiens with 7 samples.

How the data were processed

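Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts and tags open DNA, in G401 cells, a human malignant rhabdoid tumour line. Per the labels' protocols, nuclei of 100K cells were tagmented for 30 min. Of 7 samples, 3 carried a control short hairpin RNA (shCTRL), 3 a hairpin against PHF6 (shPHF6), and 1 expressed GFP for 24 h. The GFP sample is not analysed here. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

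Per the submitters' processing notes, Trim Galore 0.6.3, BWA, SAMtools, bedtools and MACS2 were used with the builds GRCh37.p13 and hg19; their roles and settings are not given in the sources used here. Each shCTRL and shPHF6 library had its own deposited peak list, so peaks were called per sample and not on pooled samples. In these lists the authors' score of a peak is a display value, the authors' fold is the enrichment at the summit over the local background of the same library, and the deposited −log10 columns hold the p-value and q-value of the peak. These values belong to each list and were used to describe, rank or filter peaks within it. Across lists they entered through the depth estimate and the thinning derived from it. The running peak numbers skipped 572 to 818 values per list, so some rows had been removed after numbering; the criterion is not given in the sources used here. Whether reads were shifted for the transposase offset or filtered for duplicates is not given in the sources used here, and either could move peak edges and weak calls.

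Depth was not stated as a read count. The fold and the −log10 p-value of a summit, as deposited by the authors, were solved together for the whole-number pileup and its local background, which worked for 99.4% to 100.0% of peaks per list. The lowest background of a list scales with sequencing depth. It was 0.348, 0.551 and 0.643 in shCTRL replicates 1 to 3 and 0.284, 0.399 and 0.735 in shPHF6 replicates 1 to 3, a range of 2.59 times. Weak peaks are therefore called more readily in the deeper libraries.

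Peaks on chromosomes 1 to 22 and X were kept. Overlapping peaks of the 6 lists (1 bp or more) were merged to 203830 regions, and a region was called in a library when any of its peaks overlapped it. Lost regions were called in 3 of 3 shCTRL and 0 of 3 shPHF6 libraries, and gained regions the reverse. A single region cannot pass a test with 3 against 3 libraries, since Fisher's exact test gives at least 0.1, so counts were set beside those of the other splits of the 6 libraries. Group values were compared by exact two-sided permutation over 20 assignments, with a smallest p of 0.1. Similarity was the Jaccard index of covered base pairs. Enrichments used two-sided Fisher's exact tests against the other regions called in exactly 3 libraries, so the background of one direction holds the all-or-none regions of the other; regions are not independent replicates, so these p-values describe the region sets and not the replicate error.

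The promoter results had been planned only for a full annotation of this build, which was not used here. After the data were seen, a partial hg19 annotation was assembled from small tables shipped with pyranges 0.1.4 and GenomicFeatures 1.54.1 (R), with gene symbols from a RefSeq table of GRCh38 matched by accession or gene identifier and none of its coordinates. It held 445 transcription start sites (TSS) of 368 protein-coding genes, which are not a random sample of genes. On average 61.2% of these TSS had a peak within 1 kb, against 13.9% and 10.8% after shifts of 50 kb to either side. Promoters were TSS ± 1000 bp. Of 466 memberships in the 18 gene lists fixed beforehand, 5 had an annotated promoter, so the list tests were not run. Bands came from circlize 0.4.16, chromosome lengths from GenomeInfoDb 1.38.1, and CpG islands of chromosome X from pyranges. The regions named were, per direction, the 12 all-or-none regions with the highest mean percentile by −log10 p within their own lists. Other genes and regions named were chosen after their values were seen.

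Alternatives fixed before the data were examined were a −log10 q of at least 5, lists cut to an equal length, 50% coverage of a region, joining across 200 bp, 500 bp windows, promoters of 500 bp, a replicate block, and each library left out in turn. Thinning of the summit pileups to the shallowest library was added after the data were seen, as was a background for the promoter odds without the regions of the other direction. On simulated lists of 60000 regions for the comparison of shCTRL with shPHF6, 100% of 200 planted lost and 100% of 200 planted gained regions were recovered. The planted regions had the same edges in every list, so this checks the code and does not measure sensitivity to weak peaks. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.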

Results

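ATAC-seq peak lists of G401 cells with a control hairpin (shCTRL, n = 3) or a hairpin against PHF6 (shPHF6, n = 3) were compared, to ask which accessible regions depend on PHF6, a PHD finger protein of chromatin that the series links to the SWI/SNF remodelling complexes. The lists held 91165, 122144 and 129952 peaks in shCTRL replicates 1 to 3 and 93381, 101995 and 155124 in shPHF6 replicates 1 to 3. Peak folds given here are the authors' per-list values.

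Neither the number of peaks nor the length they covered differed between the groups beyond the spread of the replicates. On chromosomes 1 to 22 and X, shCTRL libraries had 114289 ± 20492 peaks and shPHF6 libraries 116692 ± 33407 (SD, n = 3 each), a log2 ratio of 0.03 (exact permutation p = 0.9). The peaks covered 19.0 ± 3.10 Mb in shCTRL and 18.6 ± 4.88 Mb in shPHF6 (SD, n = 3 each), a log2 ratio of -0.04 (exact permutation p = 0.9). Covered length rose with the background of the library, from 14.8 Mb in shPHF6 replicate 1 to 24.1 Mb in shPHF6 replicate 3. These measures therefore follow depth, and a difference in accessible chromatin could be hidden by it.

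Regions common to all libraries were the stronger ones in each list. Of the 203830 merged regions, 62859 (30.8%) were called in all 6 lists, at a median percentile of 70.8 within their own lists. The 70310 regions called in a single library had a median percentile of 13.6. Regions found in at least 2 of 3 libraries numbered 103273 in shCTRL and 100150 in shPHF6, and 82419 of them were in both sets. The mean Jaccard index was 0.642 among shCTRL pairs, 0.593 among shPHF6 pairs and 0.579 between groups. Within-group pairs were 0.0378 more alike than between-group pairs (exact permutation p = 0.2, counting assignments with a difference as high; the smallest possible is 0.1).

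The all-or-none comparison found 2161 regions lost and 1948 gained with the PHF6 hairpin. The highest-ranked lost regions lay in 8q24.3 (chromosome 8, 146018876 to 146019020, mean percentile 68.0, folds 6.40 to 7.53), 11q12.1 (chromosome 11, 59349394 to 59349955, mean percentile 67.0, folds 11.9 to 14.4) and 7p22.1 (chromosome 7, 5610110 to 5610261, mean percentile 67.0, folds 6.01 to 7.25), coordinates being hg19. The other 9 lay in 9q21.32, 7p22.3, 19q13.2, 9q21.33, 16p13.3, 7q32.1, 19q13.33, 1p36.11 and 15q23. The highest-ranked gained regions lay in 1p36.23 (chromosome 1, 7981274 to 7981398, mean percentile 64.7, folds 10.7 to 19.6), 4p13 (chromosome 4, 42502124 to 42502359, mean percentile 64.2, folds 7.77 to 9.77) and 17q22 (chromosome 17, 55483096 to 55483400, mean percentile 63.7, folds 6.64 to 7.33). The other 9 lay in 15q22.33, 8q13.3, 18p11.31, 7p21.3, 20p11.21, 3p21.1, 4q28.1, 1p35.1 and 20p13. None of these 24 overlapped a transcript of the partial annotation. It held only 368 protein-coding genes, so this does not place the regions outside genes or away from promoters. Lost regions had a median percentile of 27.7 and gained regions 30.02, so both sets were mostly weak peaks.

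Among the 10 splits of the 6 libraries, the real one gave 4109 all-or-none regions and the highest other 4819. That other split set shCTRL replicate 1 with shPHF6 replicates 1 and 2, the libraries of lowest background, against the rest, and it was one-sided, with 19 regions on the first side and 4800 on the other. With a −log10 q of at least 5 the real split gave 3228 regions and the same other split 3566, of which 6 were on its first side. With lists of equal length the real split gave 5187 and the highest other 928. Leaving out a library relaxes the criterion: lost regions then numbered up to 7066 (without shCTRL replicate 1) and gained regions up to 6111 (without shPHF6 replicate 1).

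**Figure D1:**
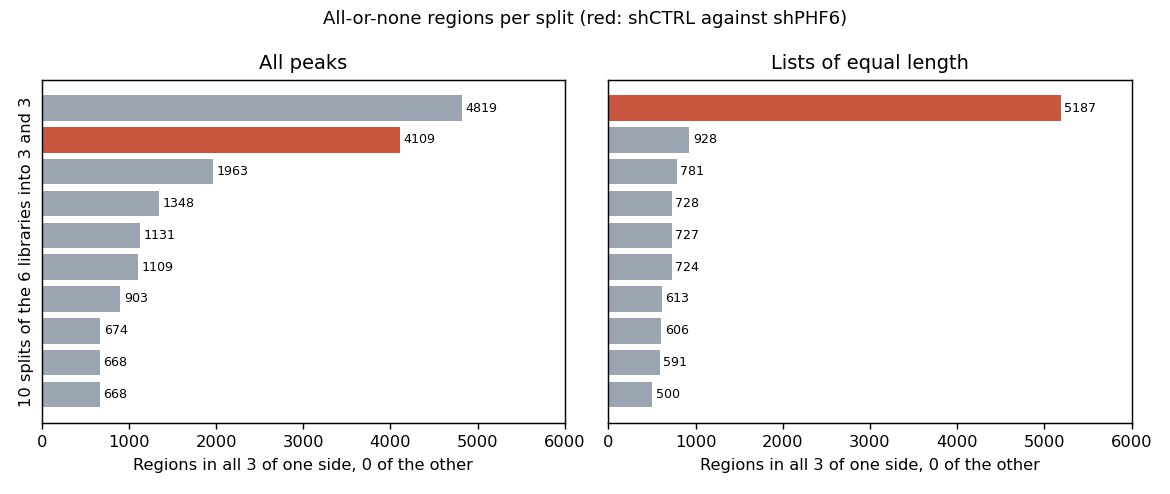
Number of regions called in all 3 libraries of one side and 0 of the other (x axis) for each of the 10 splits of the 6 libraries (1 bar each, sorted), with all peaks (left) and with lists of equal length (right). The split into shCTRL and shPHF6 (red) gave 4109 regions against 4819 for the highest other split with all peaks, and 5187 against 928 with equal lists.

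Most annotated promoters were in the same state in every library. State here is only whether a peak was called, so a change in signal that leaves the peak called is not seen. PHF6 itself (TSS at 133507342 on chromosome X) had a promoter peak in all 6 libraries, with folds of 21.33 to 33.2; a hairpin acts on the transcript, so this peak does not measure the knockdown. NOLC1, a nucleolar protein (folds 19.0 to 28.6), and MTA3, a subunit of the NuRD complex (folds 12.5 to 18.1), also had one in all 6, and MAP2 and DKC1 were called in 0 of 6. DKC1 lies in a stretch of 1.69 Mb of chromosome X (153576406 to 155270560) with no peak in any list. The partial annotation may lack some TSS of a gene, and it held 1 for MAP2. A gene at 0 may therefore have a peak at a start that is not listed. Of 368 genes, 230 had a promoter peak in all 6 libraries and 113 in 0, so 93.2% had the same state throughout. Of the 113, 17 lay in stretches of at least 1 Mb with no peak in any list. Of the other 351 genes 96 were at 0, and 92.9% had the same state throughout. Promoters were called in 244 ± 4 genes in shCTRL and 240 ± 7.21 in shPHF6 (SD, n = 3 each; exact permutation p = 0.5). Promoters lost numbered 0 of 368 and promoters gained 0 of 368. Promoters lost became 2 with lists of equal length and 4 without shPHF6 replicate 3. The share of peaks at annotated promoters was 0.427% ± 0.0523 in shCTRL and 0.371% ± 0.0487 in shPHF6 (SD, n = 3 each; exact permutation p = 0.4).

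Lost regions nevertheless lay near these TSS more often than other regions seen in 3 libraries. Of the 2161 lost regions 13 were within 1 kb of an annotated TSS, against 31 of the 15231 other regions called in exactly 3 libraries, gained ones included (odds ratio 2.97, Fisher's exact p = 0.00202). The odds ratio was 6.51 without shPHF6 replicate 3 and 6.33 with lists of equal length. Of the 31 other regions near a TSS, 21 were called only in shCTRL replicates 2 and 3 and shPHF6 replicate 3. Those are the 3 libraries of highest background, and 4800 regions were called in them alone. Of these 4800 regions 0.44% were near a TSS, against 0.60% of lost regions. Of the 1948 gained regions 0 were, against 44 of 15444 (Fisher's exact p = 0.0132), and 13 of these 44 were the lost regions. Against the 13283 regions of neither set, of which 31 were near a TSS, the odds ratio was 2.59 for lost regions (Fisher's exact p = 0.00706) and 0 for gained regions (Fisher's exact p = 0.0273). Without shPHF6 replicate 1 the odds ratio of gained regions was 0.413 (Fisher's exact p = 0.113). The 13 belonged to XPA, a nucleotide excision repair factor, APP, the amyloid precursor protein, UBE3A, a ubiquitin ligase, SRPK1, a kinase of splicing factors, CASP2, a caspase, RAP2C, a small GTPase, the histone gene H4C3, and FAAP20, VMA21, CCDC138, R3HDM1, YIPF6 and SUSD4. In 12 of these 13 genes, all but SUSD4, the promoter also had a peak called in all 6 libraries. At XPA the lost region (chromosome 9, 100459286 to 100459410, exonic, folds 5.11 to 7.30) was 76 bp from such a region, and at UBE3A (chromosome 15, 25683876 to 25683959, exonic, folds 3.71 to 4.52) 129 bp. At APP (chromosome 21, 27542276 to 27542717, intronic, folds 5.01 to 5.34) it was 163 bp away. At RAP2C, YIPF6 and SUSD4 the lost region covered the TSS itself. It was 61 bp from a region called in all 6 at RAP2C and 62 bp at YIPF6. Joined across 200 bp gaps, neither direction passed Fisher's exact test. The odds ratio was then 2.16 for lost (Fisher's exact p = 0.175) and 0 for gained regions (Fisher's exact p = 0.104).

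**Figure D2:**
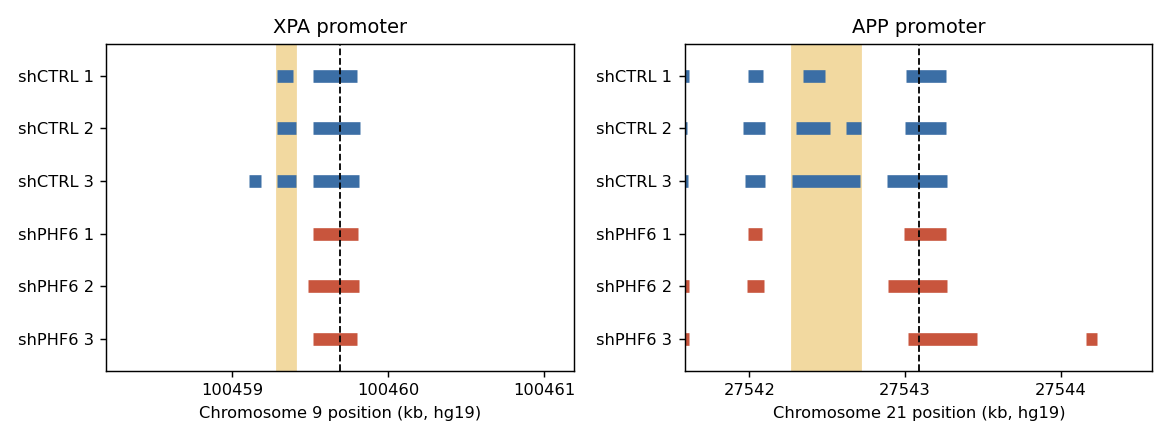
Peaks of each library (rows; blue, shCTRL; red, shPHF6) around the TSS (dashed line) of XPA and APP, with hg19 positions in kb on the x axis. The shaded lost regions, 100459286 to 100459410 at XPA and 27542276 to 27542717 at APP, hold peaks in the 3 shCTRL libraries and in 0 of the shPHF6 libraries, while the peak at the TSS is present in all 6.

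Placement beside shared regions was then compared over the genome, a comparison chosen after the data were seen. Of the lost regions 35.2% lay within 1 kb of a region called in all 6 lists, against 16.3% of gained regions and 20.5% of the 13283 regions called in 3 libraries that were neither (Fisher's exact p = 6.95e-44 for lost against gained). This gap of 18.9 percentage points was not the widest among the 10 splits of the 6 libraries. A gap as wide was found in 3 of them, the real one included, and the highest other was 19.6, with 50 regions on its smaller side. With a −log10 q of at least 5, 2 splits gave a gap as wide as the real 20.4, the highest other being 30.2 with 6 regions on its smaller side. With equal lists the real gap was 25.9 and the highest other 21.96, and after thinning they were 19.95 and 14.6. The gap of 21.96 came from the split of the 3 libraries of lowest background against the rest. There 38.1% of the 643 regions called only in the deeper 3 libraries flanked a shared region, against 40.8% of lost regions. Per library, 23.9% ± 2.30 of the regions not shared by all 6 lists flanked a shared region in shCTRL and 17.3% ± 3.28 in shPHF6 (SD, n = 3 each). All 3 shCTRL values, 21.4% to 25.9%, were above all 3 shPHF6 values, 13.6% to 19.6% (exact permutation p = 0.1, the smallest this design allows). The number of flanking regions did not separate the groups, at 11365 ± 4660 in shCTRL and 9105 ± 6773 in shPHF6 (SD, n = 3 each; exact permutation p = 0.8). It was highest in shPHF6 replicate 3 (16684), whose 88833 regions not shared by all lists were the most of any library. With lists of equal length the shares were 26.4% ± 2.80 and 18.0% ± 3.55 (SD, n = 3 each; exact permutation p = 0.1), and the numbers 7875 ± 1031 and 5369 ± 1204 (SD, n = 3 each; exact permutation p = 0.1). After thinning the numbers were 9403 ± 2676 and 7278 ± 3509 (SD, n = 3 each; exact permutation p = 0.5). Within the shared regions, the mean length covered by peaks was 223.6 ± 15.3 bp in shCTRL and 216.3 ± 22.9 bp in shPHF6 (SD, n = 3 each; exact permutation p = 0.8).

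**Figure D3:**
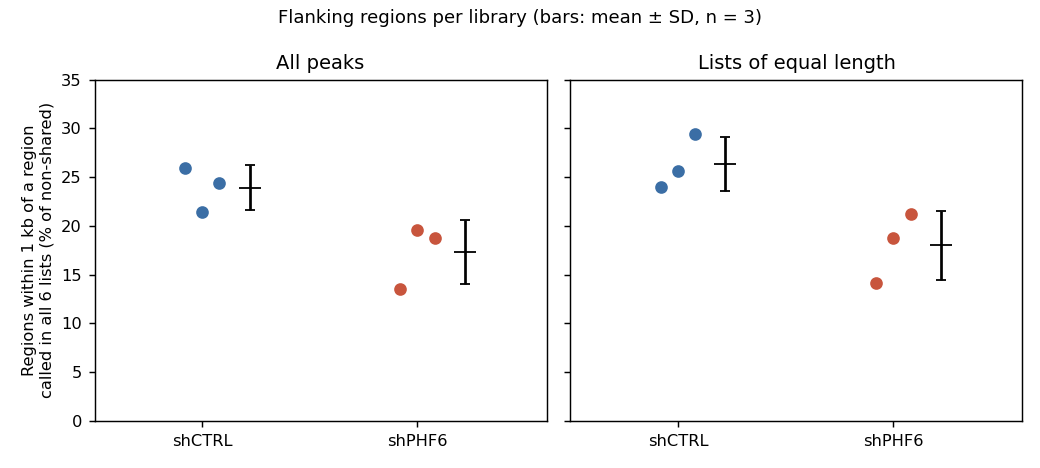
Percent of each library's regions not called in all 6 lists that lie within 1 kb of a region called in all 6 (y axis), for shCTRL and shPHF6 (points, 1 per library; bars, mean ± SD, n = 3), with all peaks (left) and lists of equal length (right). With all peaks the shCTRL libraries sit between 21.4% and 25.9% and the shPHF6 libraries between 13.6% and 19.6%.

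By chromosome, no share of peaks could pass the test after adjustment, since the smallest exact permutation p is 0.1. Chromosome 17 held 5.48% ± 0.0643 of the peaks in shCTRL and 5.30% ± 0.112 in shPHF6 (SD, n = 3 each), and chromosome 3 held 5.79% ± 0.0501 and 5.92% ± 0.0372. These were 2 of 4 chromosomes at the smallest exact permutation p of 0.1, and after Benjamini-Hochberg adjustment over 23 chromosomes the lowest value was 0.511. In a test chosen after the data were seen, lost regions were compared directly with gained regions. Chromosome 9 held 127 lost and 73 gained regions (Fisher's exact test, adjusted p = 0.04), chromosome 17 held 127 and 79 (adjusted p = 0.0800) and chromosome 20 held 60 and 83 (adjusted p = 0.0800). Neighbouring regions are not independent, so these values do not measure replicate error. The share of peaks on chromosome 9 was 4.29% in shCTRL and 4.24% in shPHF6 (exact permutation p = 0.2). Of 529 bands tested, 0 passed; the lowest adjusted p was 0.791.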

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

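Thinning, the comparison of flanks and the background without the other direction were chosen after the data were seen. With 3 libraries per group no group value could pass 0.05, so its side of the threshold says nothing about stability, and depth limits every call of a weak peak. The log2 ratio of peak number turned to -0.00685 under a −log10 q of at least 5. With each library left out in turn it ran from -0.23 to 0.17, and that of covered length from -0.27 to 0.10. Lost regions then ran from 2360 to 7066 and gained from 2194 to 6111, by construction, since 2 libraries of a group sufficed. Lost counts moved by over 1.5 times without shCTRL replicate 1 (7066), shCTRL replicate 2 (3302) and shPHF6 replicate 3 (6155), and gained counts without shCTRL replicate 2 (2996), shCTRL replicate 3 (3436), shPHF6 replicate 1 (6111) and shPHF6 replicate 2 (4742). Promoters lost ran from 0 to 4 and promoters gained from 0 to 1; promoters lost were 1 with the stricter threshold, 2 with lists of equal length, 1 with promoters of 500 bp and 1 after thinning. The promoter odds of lost regions, 2.97, were 6.33 with equal lists and 2.36 to 6.51 with a library left out (6.51 without shPHF6 replicate 3). They were 2.59 against a background without gained regions. Among the alternatives run they fell short of the threshold across 200 bp gaps (2.16, Fisher's exact p = 0.175). Those of gained regions did so at 0 across 200 bp gaps (p = 0.104), at 0 with promoters of 500 bp (p = 0.0662) and at 0.413 without shPHF6 replicate 1 (p = 0.113), all by Fisher's exact test; left-out libraries gave 0 to 0.413. The cause was not tested. With the replicate block, the log2 ratios were 0.01 for peak number and -0.05 for covered length, the promoter share differed by -0.0563 percentage points and similarity by 0.0378 (exact sign-flip p of 0.25 or more, the smallest possible). Same-numbered libraries deviated from their group means with correlations across regions of -0.0743, 0.0241 and -0.0721. Those with different numbers gave -0.0787 to 0.138. The means were of 3 libraries that differed in depth, so these values give no sign of pairing and cannot exclude it. The excess of lost over gained regions near shared regions, 18.9 percentage points, was 20.4 with the stricter threshold, 25.9 with equal lists, 19.95 after thinning and 14.2 to 21.5 with a library left out. Other splits gave as wide a gap with all peaks (19.6) and with the stricter threshold (30.2). Short sequence words and gene lists were not run, for want of a sequence and a full annotation of this build.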

Other observations

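The comparisons of CpG islands, of lost with gained regions within genes, and of peakless stretches were chosen after the data were seen, as were the tests of removed rows, of a deletion and of the gap beside shared regions in other splits.

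CpG islands of chromosome X, CG-rich stretches that often mark promoters, were compared in the same way. Of the 24 lost regions of this chromosome 8 overlapped an island, against 11 of the 170 regions called in 3 libraries that were neither lost nor gained (Fisher's exact p = 0.00053). Of the 31 gained regions 1 did (Fisher's exact p = 0.696). Of the 896 islands, 227 had a peak in all 6 lists and 635 in 0, so 96.2% had the same state throughout, 1 was lost and 0 were gained. Of the 635, 271 lay in stretches of at least 1 Mb with no peak in any list, and 94.7% of the 622 islands outside such stretches had the same state throughout. Within the partially annotated genes, APP held 2 lost and 1 gained regions, the gained one in an intron (chromosome 21, 27472091 to 27472194). Other gained regions lay in an intron of XPO1, a nuclear export receptor (chromosome 2, 61717065 to 61717156, mean percentile 53.9, folds 7.46 to 11.4), and in an intron of ETV6, an ETS family transcription factor (chromosome 12, 12170860 to 12170974, mean percentile 37.6).

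The first pattern is the set of 4109 regions called in all 3 libraries of one group and 0 of the other. Of the 10 splits, 2 gave as many, the real one included, and the highest other gave 4819; 10 splits are too few for a share under 0.05. That other split parts the libraries of lowest background from the rest, follows depth, and also exceeded the real one with the stricter threshold (3566 against 3228). Thinning may have removed depth only in part, since the lists still ran from 89544 to 122880 peaks. After thinning 4528 regions, 110.2% of the number, were all-or-none, against 2184 in that other split, still one-sided at 91 and 2093. Of the original 4109 regions 2880 (70.1%) were still all-or-none, 64.7% of the lost and 76.0% of the gained. With equal lists the counts were 5187 and 928, which with the thinned values argues against depth as the whole source, while depth for the regions that were not still all-or-none, a difference that goes with the hairpin, and handling that differed between the groups stay open.

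The second pattern is the presence of 13 lost and 0 gained regions within 1 kb of an annotated TSS (Fisher's exact p = 0.000291). Of the 10 splits 1, the real one, gave a p as small, and the other splits all gave 1.0, but several had too few regions on one side for a small p, and the split that follows depth held 21 TSS-near regions of 4800 against 0 of 19; 10 splits are too few for a share under 0.05. The imbalance held after thinning (11 and 0 regions, Fisher's exact p = 0.00114) and with equal lists (21 and 0, Fisher's exact p = 4.72e-06). It also held without shCTRL replicate 1, which had the highest promoter share (30 and 0 regions, Fisher's exact p = 0.000399). This argues against that library as the whole source. Without it, lost regions needed only shCTRL replicates 2 and 3, which are among the 3 libraries of highest background. Depth is not settled, since the thinned lists still ran from 89544 to 122880 peaks. With equal lists, 38.1% and 16.1% of the regions on the 2 sides of the split that follows depth still flanked shared regions. A candidate explanation, predicted before it was computed but after the TSS pattern was seen, is that lost regions are flanks of shared peaks. The prediction was met, since 35.2% of lost against 16.3% of gained regions lay within 1 kb of a shared region. However, 3 of the 10 splits, the real one included, gave as wide a gap (18.9 percentage points, highest other 19.6), and 5 other splits also met the prediction. The weighing against other splits was added after the result was seen, and 10 splits are too few for a share under 0.05. With equal lists and after thinning 1 split, the real one, gave as wide a gap, and with the stricter threshold 2 did. Flanks, depth, weaker flanking accessibility with the PHF6 hairpin, and a lower signal over background in the 3 shPHF6 libraries, which was not tested, therefore all stay open.

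The third pattern is 34 stretches of at least 1 Mb, 53.1 Mb in all, with no peak in any list and away from heterochromatic bands. On chromosome X, which had the fewest regions per Mb (18.1, the next lowest 35.4 on chromosome 13), lay 15 of them (29.4 Mb), including the first 2.73 Mb and 142120751 to 148621018 in Xq27.3 to Xq28, the longest at 6.50 Mb, and 2 others were 29981342 to 31082898 and 31706950 to 33394010 on chromosome 6, in the major histocompatibility region. The peak numbering skipped in 2.94% of them, which argues against removal of rows after calling. Reads shared with alternate haplotypes were predicted to empty 17q21.31, but its longest peakless stretch was 0.218 Mb, under the median of 0.265 Mb over 784 bands. This 1 band does not stand for the others. The 2 stretches of the major histocompatibility region, which also has alternate haplotypes in hg19, go with the explanation. They were weighed only after the 17q21.31 result was seen. The explanation stays open for those 2 stretches and was not tested at the others, including the 15 on chromosome X. A deletion in the cell line could not be told apart from other sources, since 0 of the stretches held a peak in any of the 6 lists by definition and no other cell line was compared; no biological explanation was tested.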
